A study of Saccharomyces cerevisiae with 48 samples.

How the data were processed

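Messenger RNA and ribosome footprints were measured in the diploid yeast strain BY4743 at 8 cell sizes from 40 to 75 fl. Each of 3 replicates per size, A, B and C, is a pool of cells of 1 size, which the labels describe as independent experimental replicates. Every pool gave 1 library per assay, so that there were 24 libraries per assay and 48 in all. Samples were grouped by assay and labelled size. Per the labels, poly(A) RNA was used for mRNA and fragments left by RNase I, depleted of ribosomal RNA, for footprints.

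The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.8, Bowtie 1.1.2, TopHat2 2.1.0, RSEM 1.2.20, SAMtools 1.3-1 and the genome build R64, without saying which tool made which table. The authors deposited 2 tables of whole-number read counts for 3301 genes, with no normalization and at least 10 reads per gene in every mRNA library. Genes under that limit were not counted, so that no statement here on counts covers them. The headers of the count tables do not name the assay. It was settled from the authors' deposited log2 table of normalized levels per library (3291 genes), whose header names an mRNA and a footprint block. All 24 columns of each count table were closest to the column of the same name in 1 block, with a median absolute difference of 0.00586 log2 for mRNA and 0.0464 for footprints, against 0.524 and 0.477 for the crossed pairs. That log2 table served no other purpose. A further table deposited by the authors holds log2 mRNA levels at each size relative to the gene's mean over sizes for 6713 ORFs, with the replicates pooled, and was only described. The authors also deposited 4 other lists of ORF names, of 144, 459, 585 and 55 names, without heading or values; what they stand for is not given in the sources used here. ORF names were paired with symbols through a reference table of assembly R64, in which 3260 of the 3301 names matched and 41 did not. How reads shared by near-identical genes, such as the paired histone and ribosomal protein genes, were assigned is not given in the sources used here, so values of such pairs are uncertain.

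Counts were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, with TMM factors computed within each assay; the filter on low counts kept all 3301 genes. For each assay an F-test compared the 8 sizes and a slope was fitted per 5 fl. Translational efficiency was tested as the interaction of assay and size in 1 model of the 48 libraries. Calls had a Benjamini-Hochberg adjusted p under 0.05. Levels are log2 CPM, counts scaled to a common library size, with a prior count of 2, given as mean ± SD over 3 libraries, and translational efficiency is the footprint level minus the mRNA level of the same pool.

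Gene lists for cell cycle phases, lipid synthesis, growth, metabolism, stress, the cell wall and cell size were fixed before the data were examined, as were the tests, the alternatives not named as later additions, and the rule for named genes. The mean level of each list was compared across sizes by a permutation test with an F statistic (100000 resamples), adjusted over the lists within each assay. Where a replicate was left out, this test used fewer resamples. Slopes of lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and at an estimated correlation, and with fry. The mating list (0 counted genes) and the meiosis list (1 counted gene) were too small for these tests. Named genes were, per assay, the 6 largest and 6 smallest slopes among the calls with a mean of at least 10 CPM and 1 sign in all 3 replicates, and the 8 largest ranges among the calls across sizes. They also included the 3 members of each list with the smallest p, and a fixed panel of cell cycle and lipid genes. Not all genes that the rule takes are printed.

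The alternatives were median-of-ratios size factors, DESeq2 1.42.0, limma-voom, no filter, the median of list members, a block for the replicate letter or the pool, and leaving out each replicate, library or size. Footprints and mRNA of 1 pool come from the same cells, which pairs them; the correlation of their deviations averaged 0.114 and was above 0.1 in 13 of 24 pools. The tests were checked on simulated counts for 3301 genes, of which 100 were changed in each size class. For mRNA, 50% of changes of 1 log2 at a single size and 98% of those of 2 log2 were recovered, with 4 false among 152 calls. Of mRNA slopes of 0.2 log2 per 5 fl 98% were recovered, with 11 false among 209 calls. For footprints the same shares were 1% and 49% at a single size (3 false among 53 calls) and 48% for slopes (5 among 153). For translational efficiency they were 4% and 20% (7 false among 31 calls) and 40% (13 among 152). Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.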

Results

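Diploid budding yeast (Saccharomyces cerevisiae, laboratory strain BY4743) growing in rich glucose medium was separated by centrifugal elutriation, which sorts cells by size and yields newborn, unbudded G1 cells. The fractions were left to grow and were harvested at 8 cell sizes from 40 to 75 fl in steps of 5 fl. Cells of 1 size were pooled until there were enough for both assays, and 3 such pools per size (replicates A, B and C) were made independently. Each pool gave 1 library of poly(A) mRNA and 1 library of ribosome footprints, the RNA fragments that ribosomes protect from nuclease, so that there were 24 libraries per assay and 48 in all. The study's title names the translational control of lipid synthesis enzymes in the cell cycle as its subject. The comparisons were therefore of mRNA, of footprints, and of footprints relative to mRNA (translational efficiency) across sizes.

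The counts covered 3301 genes, those with at least 10 reads in every mRNA library. Shares of list members given below are over the counted members only. The mRNA libraries held 248840 (40 fl, replicate B) to 5797532 (70 fl, replicate A) counted reads. Footprint libraries ranged from 26360 (65 fl, replicate C) to 5659096 reads (55 fl, replicate C). Of the 24 footprint libraries, 6 held fewer than 150000 reads. They were 50 fl replicates B (40140) and C (54111), 60 fl replicate C (116437), 65 fl replicates B (49488) and C (26360) and 70 fl replicate C (55709), and in the 65 fl replicate C library 1278 of the genes had no read.

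Groups of cell cycle transcripts changed with size, and the size of their highest mean varied. The G1/S group, targets of the transcription factors SBF and MBF that act at the start of DNA replication, was highest at 55 fl, and the core histones at 60 fl. The CLB2 cluster, expressed before mitosis, was highest at 65 fl, and genes of the M/G1 transition at 75 fl. The next size was close in 3 groups, with centred means of 0.76 and 0.70 at 55 and 60 fl for G1/S, 1.35 at both 60 and 65 fl for the histones, and 0.73 and 0.72 at 65 and 70 fl for the CLB2 cluster. In the authors' deposited table of pooled mRNA the medians of these groups were highest at 55, 65 and 75 fl. Neither the order nor the separation of these peaks was tested. ALK1, a mitotic protein kinase gene of the CLB2 cluster, had the steepest rise among the named genes, from 4.96 ± 0.70 log2 CPM (SD, n = 3) at 40 fl to 9.06 ± 0.21 at 65 fl. SIC1, the inhibitor of B-type cyclin kinase that is made at the end of mitosis, rose from 6.53 ± 0.44 at 40 fl to 9.74 ± 0.26 at 75 fl (SD, n = 3). Their slopes were 0.73 (SE 0.09) and 0.44 (SE 0.03) log2 per 5 fl, with edgeR adjusted p of 4.61e-07 and 1.88e-11.

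All 8 counted members of the G1/S group (37 listed) differed across sizes, adjusted over all genes and adjusted over the list alone, and 2 of them also rose along size. RAD27 (flap endonuclease) climbed from 5.97 ± 0.74 at 40 fl to 8.69 ± 0.08 at 55 fl and PRI2 (primase) from 6.12 ± 0.48 at 40 fl to 8.59 ± 0.70 at 60 fl (SD, n = 3 each). The mean level of the group changed by 1.96 log2 between 40 and 55 fl (permutation test over the 24 libraries, adjusted p = 0.000383). CLB5, an S-phase cyclin gene, differed across sizes with a smaller range of 0.94 and its highest level at 55 fl (edgeR adjusted p = 0.0133). CLN3, the cyclin gene that acts upstream of SBF and MBF, had a range of 0.83 and did not pass the test (edgeR adjusted p = 0.466).

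All 7 counted core histone genes differed across sizes and all 7 rose along size, adjusted over all genes and adjusted over the list alone. HTA2, which encodes histone H2A, went from 6.49 ± 1.01 at 40 fl to 10.94 ± 0.33 at 60 fl, and HHF2, which encodes histone H4, from 6.60 ± 0.11 to 10.28 ± 0.43 at 65 fl (SD, n = 3). The list as a whole spanned 3.18 log2 (permutation test, adjusted p = 0.000115, from the smallest p that the permutations can give, 1e-05). In the CLB2 cluster 9 of 12 counted members (31 listed) differed across sizes and 9 rose, or 9 and 10 adjusted over the list alone. SPO12, a regulator of mitotic exit, rose from 5.26 ± 0.33 at 40 fl to 8.36 ± 0.32 at 75 fl, and MYO1, the myosin of the cytokinetic ring, from 6.59 ± 0.38 to 9.46 ± 0.15 at 65 fl (SD, n = 3). The cluster spanned 1.79 log2 (permutation test, adjusted p = 0.000115). All 11 counted spindle and kinetochore genes (34 listed) rose, among them TUB2 (beta-tubulin, slope 0.36, SE 0.06) and KAR3 (kinesin, slope 0.25, SE 0.06). Of the 11, 8 differed across sizes (10 adjusted over the list alone). Their mean level spanned 1.33 log2 (permutation test, adjusted p = 0.000632). Of the 9 counted M/G1 genes (26 listed) 3 differed across sizes and 4 rose, with the same numbers adjusted over the list alone. The mean of these genes spanned 1.16 log2 (permutation test, adjusted p = 0.00138). Among them CTS1, the chitinase that separates mother and daughter, went from 5.27 ± 0.38 at 45 fl to 8.86 ± 0.67 at 75 fl (SD, n = 3).

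**Figure D1:**
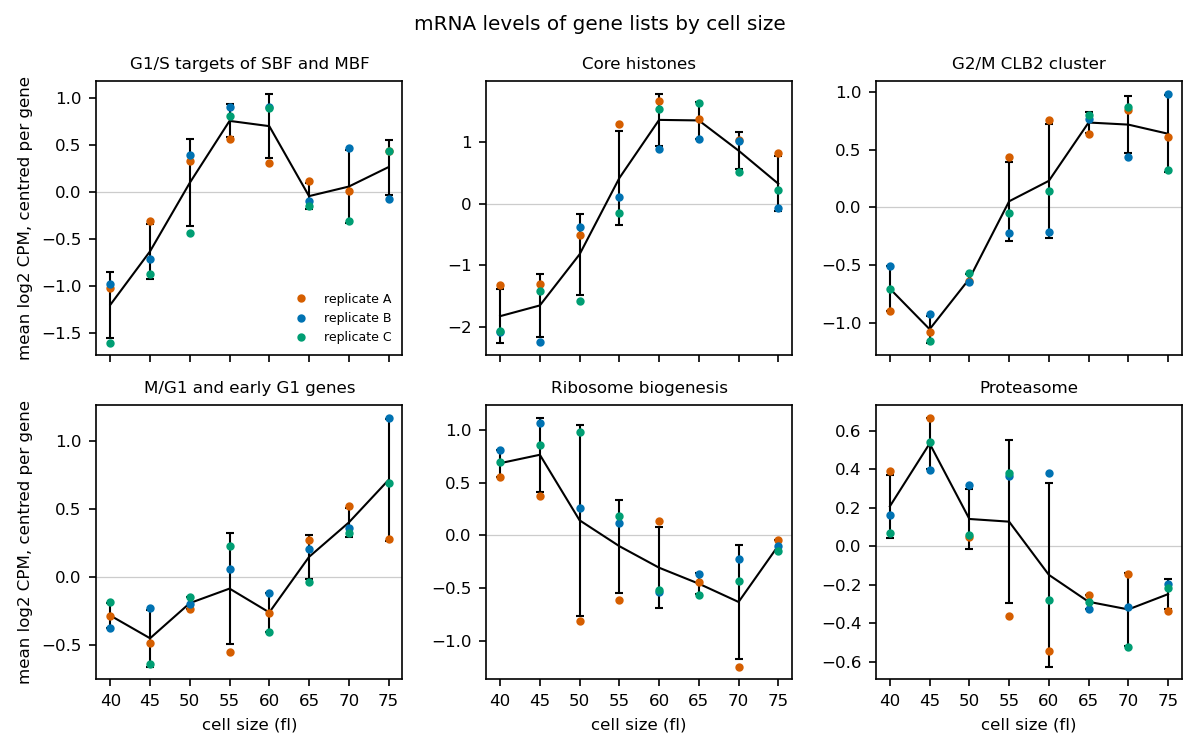
Mean mRNA level of 6 gene lists (log2 CPM, each gene centred on its mean over the libraries) against cell size in fl, with 1 point per library coloured by replicate, lines through the mean of each size and bars of 1 SD (n = 3). The G1/S list is highest at 55 fl, the core histones at 60 fl, the CLB2 cluster at 65 fl and the M/G1 list at 75 fl, whereas ribosome biogenesis and proteasome genes are highest at 45 fl.

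Mean transcript levels of the ribosome biogenesis and proteasome lists were highest at 45 fl and lowest at 70 fl. Of 89 ribosome biogenesis genes 72 fell along size and none rose (73 fell adjusted over the list alone), and 45 differed across sizes (59 adjusted over the list alone). UTP8 (small subunit processing) went from 8.69 ± 0.27 at 40 fl to 6.50 ± 0.36 at 70 fl, and CIC1 (large subunit assembly) from 9.57 ± 0.19 to 7.79 ± 0.60 (SD, n = 3). TIF6, which also acts in large subunit assembly, fell with a slope of -0.34 (SE 0.04). DIM1, an rRNA dimethylase gene, had a slope of -0.41 (SE 0.04, edgeR adjusted p = 6.11e-08). Of 37 translation factor genes 14 fell and 2 rose (16 and 2 adjusted over the list alone), and 7 differed across sizes under both adjustments. SUI3, a subunit of initiation factor eIF2, fell from 11.28 ± 0.13 at 40 fl to 9.20 ± 0.11 at 65 fl (SD, n = 3). Of 32 proteasome genes 22 fell and none rose under both adjustments, and 10 differed across sizes (12 adjusted over the list alone), with RPT2 at 11.12 ± 0.19 at 45 fl and 9.50 ± 0.13 at 70 fl (SD, n = 3). The list means spanned 1.40 log2 for ribosome biogenesis and 0.86 for the proteasome (permutation tests, adjusted p = 0.0304 and 0.0283). That of the translation factors spanned 0.56 (adjusted p = 0.0891). Genes for cytosolic ribosomal proteins had few calls: 24 of 138 rose and none fell (17 and 0 adjusted over the list alone), and 14 differed across sizes (6 adjusted over the list alone). Over all 3301 genes 642 rose, 730 fell and 856 differed across sizes, so the share that rose was not above that of all genes. RPL22A, the member with the smallest p across sizes, rose from 9.25 ± 0.17 at 40 fl to 11.53 ± 0.23 at 65 fl (SD, n = 3), while the median slope of the list was 0.03. Their mean level spanned 0.65 log2 without passing the test (permutation test, adjusted p = 0.21). Of 51 mitochondrial ribosomal protein genes 13 rose, 3 fell and 5 differed across sizes, or 9, 3 and 1 adjusted over the list alone (permutation test of the list mean, adjusted p = 0.701).

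Each of the 4 lipid synthesis lists held both rising and falling genes. Of 15 fatty acid genes 6 fell and 4 rose (6 and 5 adjusted over the list alone), and 10 differed across sizes under both adjustments. Those that fell included ACC1 (acetyl-CoA carboxylase, the first committed step), from 10.27 ± 0.22 at 40 fl to 8.11 ± 0.13 at 65 fl, and OLE1 (the fatty acid desaturase), from 11.42 ± 0.35 to 6.80 ± 0.39 (SD, n = 3). OLE1 varied between replicates at 50 fl, where its SD was 2.64. FAA3, which activates fatty acids, rose with a slope of 0.18 (SE 0.05, edgeR adjusted p = 0.00243). The median slope of the list was 0.04 and its mean -0.04, so the list has no single direction (permutation test of the list mean, adjusted p = 0.0644). Of 17 phospholipid genes 7 fell and 3 rose (8 and 3 adjusted over the list alone), 4 differed across sizes under both adjustments, and the list mean spanned 0.67 log2 (permutation test, adjusted p = 0.00215). CHO1, the phosphatidylserine synthase, fell from 9.16 ± 0.29 at 40 fl to 6.74 ± 0.32 at 75 fl, and OPI1, the repressor of phospholipid genes, from 8.08 ± 0.21 to 6.63 ± 0.28 at 60 fl (SD, n = 3). Of 19 ergosterol genes 7 rose, 2 fell and 6 differed across sizes (8 across sizes adjusted over the list alone), with ERG3 at 6.88 ± 0.81 at 40 fl and 9.08 ± 0.20 at 55 fl (SD, n = 3). Of 13 sphingolipid genes 1 rose (LAC1, a ceramide synthase), 1 fell (ORM2) and 2 differed across sizes, under both adjustments. Neither list mean passed the permutation test (adjusted p = 0.173 and 0.224).

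Among the lists for metabolism, chaperones, stress, the cell wall and cell size, the means of the amino acid and Hsf1 lists passed the test. Over all 3301 genes, 642 rose and 730 fell. Of 37 amino acid genes 17 rose, 2 fell and 13 differed across sizes (17, 3 and 14 adjusted over the list alone), with HIS4 going from 5.47 ± 0.27 at 45 fl to 7.84 ± 0.39 at 70 fl (SD, n = 3), and the list mean spanned 0.53 log2 (permutation test, adjusted p = 0.0304). GCN4, the activator of these genes, did not pass (edgeR adjusted p = 0.236). Of 19 protein folding genes controlled by Hsf1 10 rose, 1 fell and 7 differed across sizes (10, 1 and 9 adjusted over the list alone), among them HSP82 (slope 0.24, SE 0.06), and the list mean spanned 0.77 log2 (permutation test, adjusted p = 0.0413). Of 23 genes of glycolysis and fermentation 11 rose, none fell and 7 differed across sizes (11, 0 and 8 adjusted over the list alone). HXT4, a glucose transporter gene, rose from 5.87 ± 0.22 at 40 fl to 8.73 ± 0.42 at 75 fl (SD, n = 3). Of 35 TCA cycle and respiration genes 12 rose, 1 fell and 8 differed across sizes under both adjustments. Of 22 cell wall genes 6 rose, 2 fell and 9 differed across sizes (5, 2 and 10 adjusted over the list alone), with PSA1 (GDP-mannose synthesis) at 8.20 ± 0.18 at 40 fl and 10.92 ± 0.48 at 70 fl (SD, n = 3). Of 30 Msn2 and Msn4 stress targets 3 rose, 6 fell and 8 differed across sizes (2, 5 and 11 adjusted over the list alone). HSP12 was highest at 50 fl, at 9.86 ± 1.24 (SD, n = 3). Of 18 regulators of Start and cell size 6 rose, 2 fell and 5 differed across sizes (7, 2 and 6 adjusted over the list alone). Of 4 quiescence genes 1 differed across sizes and none had a slope that passed, under both adjustments. The means of these last 6 lists did not pass the permutation test (adjusted p = 0.224, 0.177, 0.277, 0.552, 0.0676 and 0.248).

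In the edgeR tests 856 of 3301 genes differed across sizes, 738 of them by more than 1 log2, and 1372 had a slope along size, 642 rising and 730 falling. Of the 856, 269 were highest at 40 fl and 150 at 45 fl, against 21 at 50 fl, 42 at 55 fl, 66 at 60 fl, 110 at 65 fl, 108 at 70 fl and 90 at 75 fl. The steepest falls among the named genes were those of RCK1, a protein kinase gene, from 9.32 ± 1.25 at 40 fl to 4.12 ± 0.33 at 65 fl, and BIO2 (biotin synthase), from 9.36 ± 0.22 to 5.75 ± 0.15 (SD, n = 3). As a test of lists against other genes, camera with its preset correlation called 16 of 23 lists along size and none with an estimated correlation. Under the estimated correlation the adjusted p was 0.164 for the CLB2 cluster and 0.675 for cytosolic ribosomal proteins. It was 0.432 for the G1/S, translation factor, glycolysis and TCA cycle lists, and 0.272 for the other lists that had been called. Of the lists called with the preset correlation, fry, which sets no list against other genes, passed all but cytosolic ribosomal proteins (adjusted p = 0.182). The adjusted p in fry of those that passed ranged from 1.68e-06 (CLB2 cluster) to 0.016 (glycolysis and TCA cycle). The count across sizes was 221 without replicate B, 110 without replicate C and 1394 with DESeq2, and the count of slopes was 887 without replicate C. Of the 11 list means that passed the permutation test, those of the G1/S, core histone and CLB2 lists also passed without replicate B and without replicate C, and the other 8 in neither case. Without replicate A the amino acid list did not pass (permutation test, adjusted p = 0.168), whereas the sphingolipid list did (0.0269). With the median of the members in place of the mean 9 of the 11 passed, and the M/G1 and Hsf1 lists did not (both adjusted p = 0.0662).

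The cyclin genes CLN1, CLN2 and CLB2 fell outside the counted set, which holds only genes with at least 10 reads in every mRNA library. In the authors' deposited table of pooled mRNA levels (log2 relative to each gene's mean over sizes, 1 value per size, no replicates) the G1 cyclin genes CLN1 and CLN2 went from -3.83 at 40 fl and -3.31 at 45 fl to 1.07 and 1.14 at 60 fl. RNR1, which encodes ribonucleotide reductase, went from -2.53 at 40 fl to 1.06 at 55 fl in the authors' deposited table. There the mitotic cyclin gene CLB2 went from -3.67 at 45 fl to 1.02 at 70 fl, and its fellow mitotic genes SWI5 and CDC20 from -3.12 and -2.46 at 45 fl to 0.92 and 1.34 at 75 fl. EGT2, a daughter-specific gene of early G1, had the widest span of the genes given here, from -4.57 at 45 fl to 1.69 at 75 fl. WHI5, the inhibitor of SBF, went from -2.28 at 40 fl to 0.82 at 70 fl. The median of the 37 G1/S genes in the authors' deposited table was -1.46 at 40 fl and 0.71 at 55 fl, and that of the 31 CLB2 cluster genes was -2.08 at 45 fl and 0.84 at 75 fl. These pooled values were only described and not tested.

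**Figure D2:**
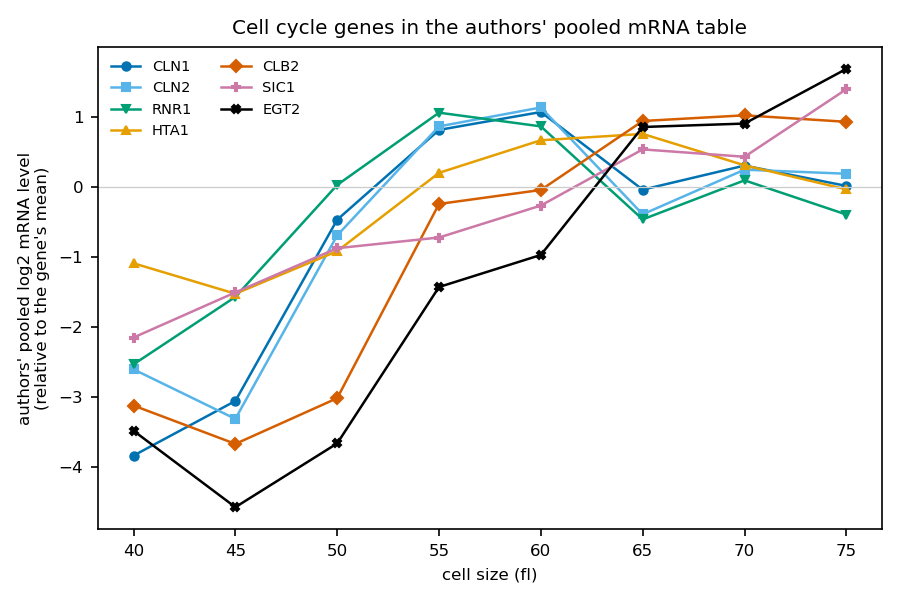
Level of 7 cell cycle genes in the authors' deposited table of pooled mRNA (log2 relative to each gene's mean over the 8 sizes) against cell size in fl, 1 pooled value per size and no error. CLN1 and CLN2 are highest at 60 fl (1.07 and 1.14), RNR1 at 55 fl (1.06), CLB2 at 70 fl (1.02) and EGT2 at 75 fl (1.69).

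Over all 3 replicates, ribosome footprints gave few genes that differed with size. In edgeR 11 genes differed across sizes, and 10 of these were highest at 60 fl. Among them PAP2, a poly(A) polymerase of RNA surveillance, stood at 9.60 ± 3.66 log2 CPM at 60 fl and 5.91 ± 0.74 at 40 fl, and RGA2, a GTPase activator of Cdc42, at 8.77 ± 2.81 and 5.19 ± 0.26 (SD, n = 3). NGL1, LAM6, GPI14, SRL2, CSF1 and NQM1 were likewise highest at 60 fl, with SDs there from 2.28 (LAM6) to 3.06 (GPI14). These 10 genes averaged 9.78 and 10.02 in the 60 fl libraries of replicates A and C but 5.19 in that of replicate B, and 9.27 in the 70 fl library of replicate A. In 3 libraries, 60 fl A and C and 70 fl A, the single gene FAR11 took 9.65%, 25.1% and 16.3% of the counted reads, against at most 0.771% in the other footprint libraries. FAR11 was singled out after its values were seen. No gene had a slope along size that passed (0 of 3301 in edgeR, 188 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom). Across sizes 126 genes had an unadjusted p under 0.05, and DESeq2 called 52 and limma-voom 0. No list mean passed the permutation test (adjusted p from 0.793 to 0.824), and adjusted over the list alone only 1 spindle gene and 1 fatty acid gene differed across sizes. The 11 calls became 0 without 60 fl A or without 60 fl C.

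The replicates differed in the direction in which footprints changed. Mean core histone footprints fell with size in replicate A by a slope of -0.47 log2 per 5 fl (exact p = 0.00868, adjusted over lists 0.0362) and rose in B by 0.44 (exact p = 0.00491, adjusted 0.0282). In C the slope was 0.58 and did not pass (exact p = 0.0723, adjusted 0.333). For ribosome biogenesis it was -0.29 in B (exact p = 0.000198, adjusted 0.00456), and neither -0.45 in C (exact p = 0.0116, adjusted 0.133) nor 0.22 in A (exact p = 0.136, adjusted 0.174) passed. The median slope over the genes of the core histone list was -0.43 in replicate A, 0.47 in B and 0.55 in C, and that of ribosome biogenesis was 0.21, -0.29 and -0.42, in log2 per 5 fl. For the CLB2 cluster it was -0.27 in A, 0.29 in B and -0.01 in C. For mRNA of the same pools the histone medians were 0.39, 0.43 and 0.45. The slope of replicate A differed from that of the other replicates for 877 genes in footprints (503 higher, 374 lower, edgeR interaction test) and for 0 genes in mRNA (347 at an unadjusted p under 0.05). For replicates B and C the same test gave 0 genes in either assay (219 for B in both assays, and 38 in mRNA and 326 in footprints for C, at an unadjusted p under 0.05). Neither DESeq2 nor limma-voom was run on this interaction.

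To place each library on a common scale, its deviations were correlated across genes with the mRNA size slope taken from the other replicates. Along labelled size this position rose in the mRNA of replicates A (r = 0.807, exact permutation p = 0.0148), B (r = 0.896, exact p = 0.00441) and C (r = 0.929, exact p = 0.00124), each over 8 libraries and two-sided. In footprints it rose in B (r = 0.954, exact p = 0.000694) and C (r = 0.98, exact p = 0.000149) and fell in A (r = -0.872, exact p = 0.000992). Spearman's rho was 0.714, 0.905 and 0.905 for mRNA (exact p = 0.0576, 0.00456 and 0.00456) and -0.952, 0.929 and 0.976 for footprints of A, B and C (exact p = 0.00114, 0.00223 and 0.000397). Adjusted over the 6 relations, the p of r was 0.00186 for the footprints of A, and all 6 were at most 0.0148. Without the 40 and 75 fl libraries r was -0.849 for the footprints of A (exact p = 0.00556), 0.933 for B and 0.961 for C.

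**Figure D3:**
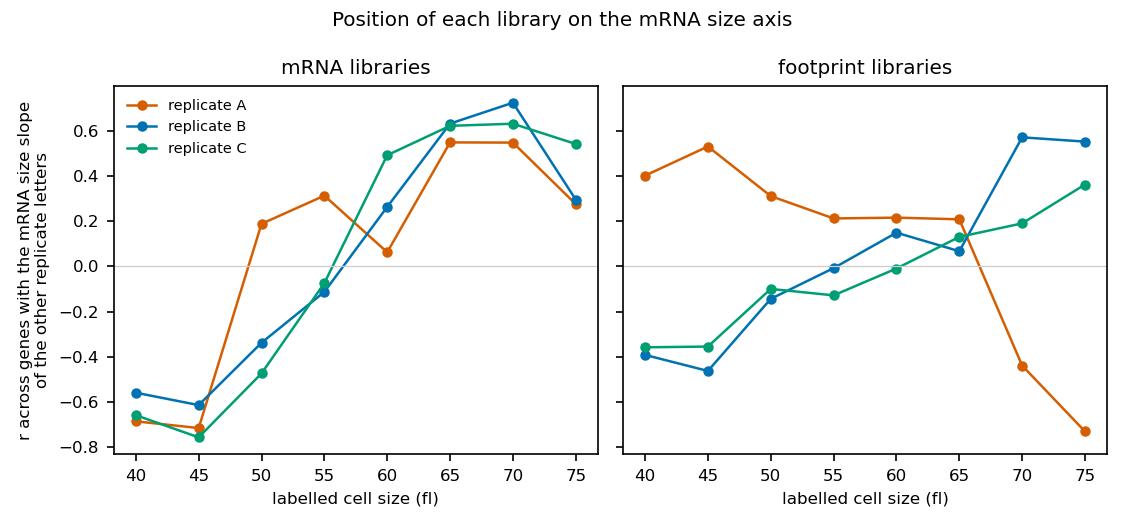
Position of each library on the mRNA size axis, as the correlation across genes of its deviations with the mRNA size slope of the other replicates, against labelled cell size in fl, for mRNA (left) and footprint (right) libraries. Points are single libraries joined by replicate; the footprint position of replicate A goes from 0.40 at 40 fl to -0.73 at 75 fl, while those of B and C go from -0.39 and -0.36 to 0.55 and 0.36.

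Without replicate A, footprints of core histone and glycolysis genes rose with size and those of ribosome biogenesis genes fell. Leaving out each replicate in turn was set out before the data were examined, but this fit was singled out after its results were seen. Of 3301 genes 795 then had a slope (297 rising, 498 falling) and 621 differed across sizes in edgeR, with 2 libraries per size. At 50 and 65 fl both of these were shallow (26360 to 54111 reads). Leaving out the 6 shallow libraries as well leaves 6 sizes, of which 60 and 70 fl keep only the library of replicate B. Of the 795, 501 also had an mRNA slope that passed and 497 of these had the same direction. Replicate A was the one whose footprint slopes ran against its mRNA slopes (r = -0.513), so leaving it out favours such agreement. All 7 core histone genes rose, among them HHF2 (slope 0.60, SE 0.08, edgeR adjusted p = 2.64e-06) and HTA2 (0.56, SE 0.08, edgeR adjusted p = 3.15e-06). Of the 12 CLB2 cluster genes 7 rose, SPO12 by 0.56 per step (SE 0.10), as did 6 of 11 spindle genes, TUB2 by 0.53 (SE 0.09). Of 89 ribosome biogenesis genes 85 fell and none rose, with TIF6 at -0.28 (SE 0.06) and CIC1 at -0.38 (SE 0.07). Of 23 glycolysis and fermentation genes 21 rose and 1 fell, with PDC1, pyruvate decarboxylase, at 0.55 (SE 0.04, edgeR adjusted p = 1.39e-11). Of 35 TCA cycle genes 18 rose and 1 fell (CIT2), of 138 cytosolic ribosomal protein genes 68 rose and none fell, and of 32 proteasome genes 1 fell. Of 8 G1/S genes 2 rose and of 9 M/G1 genes 3 rose. Of 30 stress targets 11 rose and 2 fell, and HSP12 rose by 0.49 (SE 0.12). ACC1, FAS1 and FAS2 footprints all fell, and so did those of OLE1 (-0.63, SE 0.09, edgeR adjusted p = 0.000154).

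In this fit 6 list means passed the permutation test, those of the core histones and glycolysis (both adjusted p = 0.0138), the TCA cycle (0.0284), the lipid enzymes named in the title (0.0351), and the stress and Hsf1 targets (both 0.0456). The means of ribosome biogenesis (0.0526), spindle (0.112), CLB2 cluster (0.157), G1/S and proteasome (both 0.223) and M/G1 genes (0.483) did not pass. With an estimated correlation camera called 5 lists, namely ribosome biogenesis (adjusted p = 0.00238), spindle genes (0.0121), the CLB2 cluster and glycolysis (both 0.0382) and core histones (0.0465). Of the other lists called with the preset correlation, the TCA cycle and Hsf1 targets had an adjusted p = 0.091 with the estimated correlation, the cell wall 0.0915, the stress targets and cytosolic ribosomal proteins 0.271, the title's lipid enzymes 0.301 and the proteasome 0.384. Over all 3 replicates camera called 8 lists in footprints with its preset correlation and none with the estimated one (adjusted p = 0.558, and 0.586 for cytosolic ribosomal proteins), and fry called none. Within single replicates the slopes that passed in edgeR numbered 20 in A (11 rising, 9 falling), 705 in B (256 rising, 449 falling) and 129 in C (79 rising, 50 falling).

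**Figure D4:**
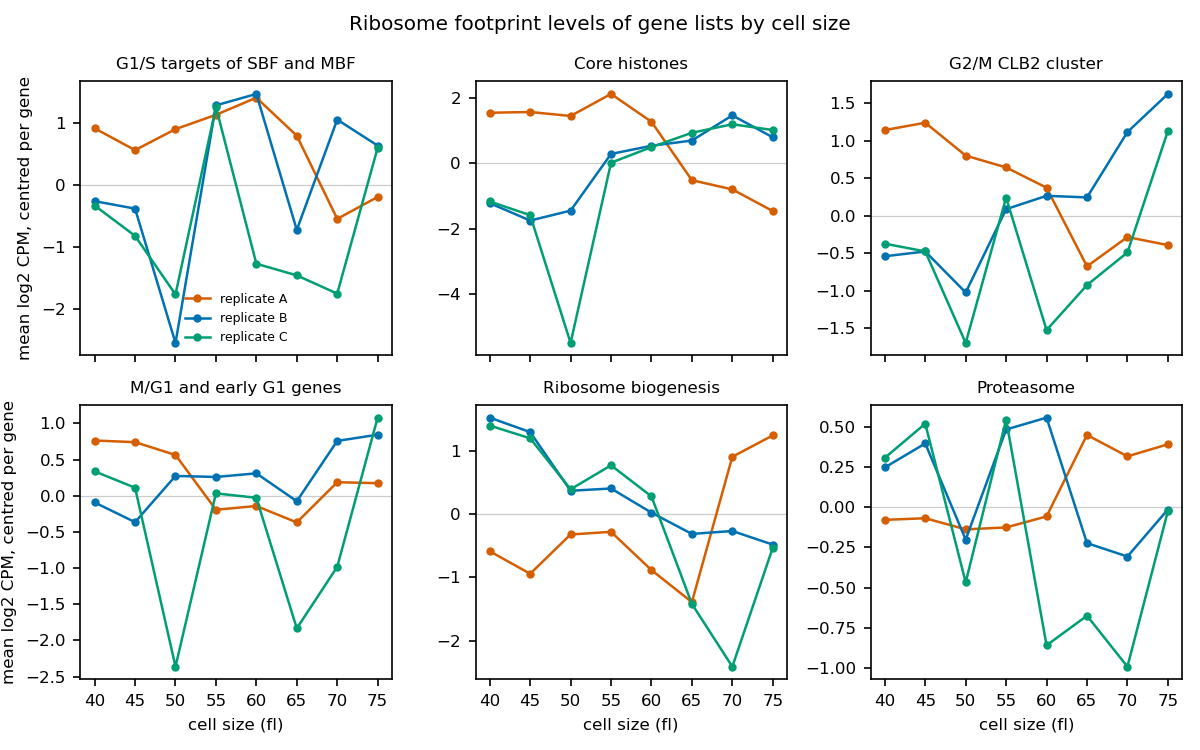
Mean ribosome footprint level of 6 gene lists (log2 CPM, each gene centred on its mean over the libraries) against cell size in fl, 1 point per library joined by replicate. The median slope of the core histones is -0.43 log2 per 5 fl in replicate A, 0.47 in B and 0.55 in C, and that of ribosome biogenesis is 0.21, -0.29 and -0.42.

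Translational efficiency, the footprint level of a gene relative to its mRNA, showed few genes that differed across sizes. In 1 edgeR model over the 48 libraries 11 genes had footprints that changed differently from their mRNA across sizes; in simulated counts 7 of 31 such calls were false. PAP2, RGA2, LAM6, NGL1 and GPI14, already named for their footprints at 60 fl, were among these, as were ALK1 (highest at 50 fl), FMP16 (highest at 40 fl) and the mitochondrial intron gene AI1 (highest at 50 fl). Their ranges over sizes were 5.17 (AI1) to 7.67 (PAP2) log2, with SDs at single sizes as large as 4.58 (LAM6 at 70 fl). At 50 fl the footprint libraries of replicates B and C held only 40140 and 54111 reads, and 901 and 1396 genes had no read there. No gene had a translational efficiency slope that passed (0 in edgeR, 416 at an unadjusted p under 0.05, 132 in DESeq2, 0 in limma-voom). Across sizes 189 had an unadjusted p under 0.05, and DESeq2 called 36 and limma-voom 0. With the pool that both libraries share as a block, 0 genes passed in either test.

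No gene group changed its translational efficiency by a test that held under all its forms. None of the 23 list means passed the permutation test (lowest adjusted p = 0.574). Adjusted over the list alone, all 7 core histones and 4 CLB2 cluster genes had falling slopes, with medians of -0.38 and -0.14 log2 per 5 fl, and 4 phospholipid genes rose and 1 fell. The median histone slope was -0.78 in replicate A, 0.04 in B and 0.15 in C. Camera called 9 lists with its preset correlation. With the estimated correlation none passed, at adjusted p = 0.538 for core histones, the CLB2 cluster, spindle, amino acid and proteasome genes and the title's lipid enzymes, 0.541 for stress targets and mitochondrial ribosomal proteins, and 0.557 for translation factors. Without replicate A 35 genes differed across sizes and 29 had a slope (6 rising, 23 falling). The steepest of these was PCK1, which makes the enzyme that commits carbon to glucose synthesis, at -0.72 per step (SE 0.10, edgeR adjusted p = 1.27e-05). All 7 histone genes then failed the edgeR tests. Their median slope in that fit was -0.11, opposite in sign to the medians of B and C taken singly, so no direction is given. Their list mean passed the permutation test across sizes, as the only list to do so (adjusted p = 0.0184). Counts without single pools ranged from 0 to 20 across sizes and from 0 to 7 for slopes.

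ACC1, FAS1 and FAS2 are the enzymes in the study's title that make malonyl-CoA and build fatty acids from it. Relative to the other counted mRNA, their mRNA levels had falling slopes along size, and amounts per cell were not measured. FAS2 mRNA in replicate B was higher at 75 fl (8.62 log2 CPM) than at 40 fl (8.41). Every other gene and replicate had the lower mRNA level at 75 fl. The footprint slopes of the 3 genes were 0.15 to 0.18 log2 per 5 fl in replicate A (exact p = 0.0545 to 0.0608) and -0.16 to -0.24 in B and C (exact p = 0.0141 to 0.0852). The mRNA slopes in B and C were -0.15 to -0.29 (exact p = 0.0133 to 0.281). They lie on chromosome XIV from 654673 to 661374 (ACC1), chromosome XI from 100671 to 106826 (FAS1) and chromosome XVI from 108652 to 114315 (FAS2) of build R64. All 3 mRNAs fell, adjusted over all genes and adjusted over the list alone. This list comes from the study's title and may have been chosen on these samples, so its direction is not taken as independent evidence. FAS1 went from 9.83 ± 0.57 at 40 fl to 7.92 ± 0.41 at 60 fl and FAS2 from 8.47 ± 0.57 to 6.58 ± 0.31 at 65 fl (SD, n = 3), with edgeR adjusted p across sizes of 0.000274 for ACC1, 0.002 for FAS1 and 0.00931 for FAS2. Averaged over these opposite signs, their footprints ranged by 0.83, 0.84 and 0.77 log2 and did not pass (edgeR adjusted p = 1 for all 3). Translational efficiency of ACC1 was 0.62 ± 0.35 log2 at 40 fl and 2.85 ± 0.20 at 60 fl, that of FAS1 2.04 ± 1.08 and 3.86 ± 0.11 and that of FAS2 3.10 ± 1.27 and 4.74 ± 0.36 (SD, n = 3). These differences did not pass the test across sizes (edgeR adjusted p = 0.562 for ACC1 and 1 for FAS1 and FAS2). Nor did the mean of the 3 genes, which spanned 1.90 log2 from 40 to 60 fl (permutation p = 0.046, adjusted over 23 lists 0.574).

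Relative to its own mean, the average efficiency of the 3 genes at 60 fl was 1.08 in replicate A, 0.81 in B and 1.22 in C, and at 40 fl it was -1.89, -0.41 and -0.27. These sizes had the highest and lowest mean over the same libraries, so agreement of the replicates there is no separate support. The 60 fl footprint libraries of A and C were among those with the FAR11 excess. At 75 fl the replicates parted, at 1.07, -0.68 and 0.17. Along size the average slope was 0.15 log2 per 5 fl (permutation p = 0.0325). Within replicates the slope was 0.35 in A (exact p = 0.0317), 0.03 in B (exact p = 0.759) and 0.06 in C (exact p = 0.574), and the slopes in B and C did not pass. In ACC1 the mRNA slope was -0.19 in A, -0.28 in B and -0.29 in C, and the footprint slope 0.15, -0.16 and -0.17, and the other 2 genes had the same signs. Without replicate A all 3 footprint levels fell (FAS2 at -0.22, SE 0.04, edgeR adjusted p = 5.56e-05), and no slope of their translational efficiency passed (edgeR adjusted p = 0.683 for ACC1, 0.993 for FAS1 and 0.647 for FAS2).

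**Figure D5:**
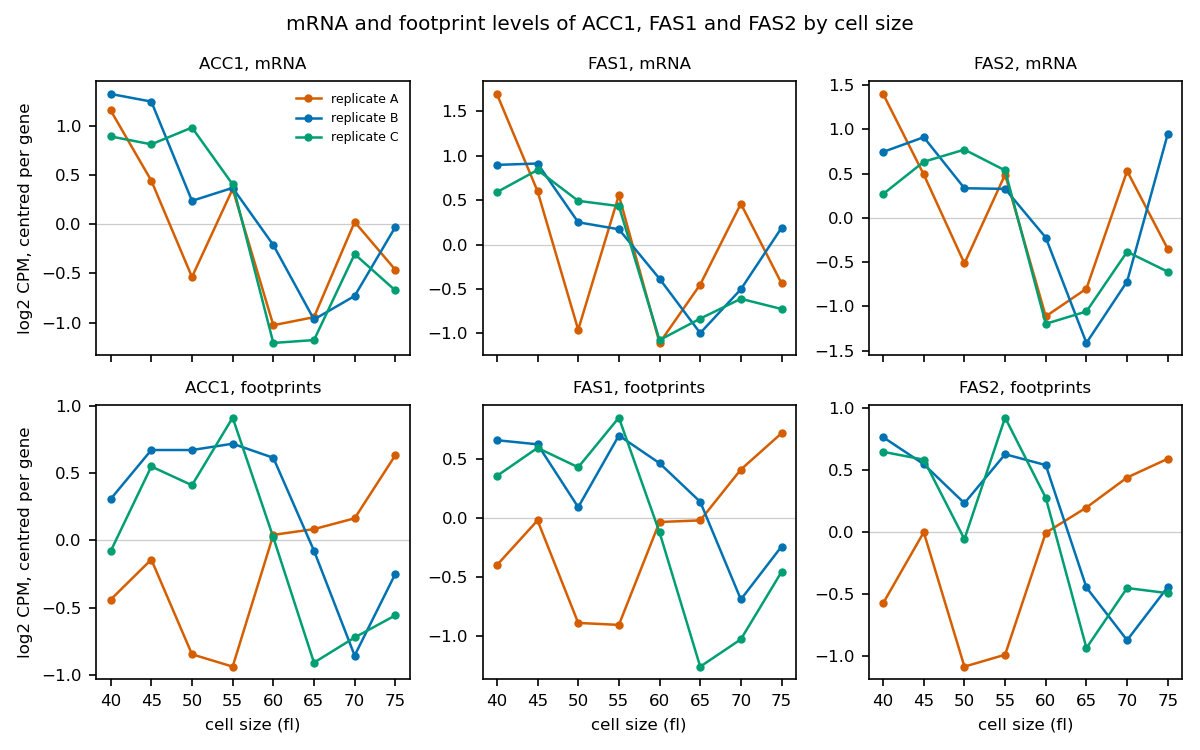
Levels of ACC1, FAS1 and FAS2 (log2 CPM, centred on each gene's mean) against cell size in fl, for mRNA (top) and ribosome footprints (bottom), 1 point per library joined by replicate. All 3 mRNAs are lower at 65 fl than at 40 fl in each replicate, and all 3 footprint levels are higher at 75 fl than at 40 fl in replicate A and lower in B and C.

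Across genes, the footprint slope went with the mRNA slope when all replicates were used (Pearson r = 0.465, Spearman's rho = 0.519, 3301 genes, which are not independent replicates). Within replicates r was -0.513 in A, 0.662 in B and 0.508 in C. Footprints of replicate A also ran against the mRNA slopes of B (r = -0.663) and C (r = -0.683), whereas the mRNA slopes of A went with the footprint slopes of B (r = 0.421) and C (r = 0.292).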

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

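The tests of the footprints of replicate A, of the peak at 60 fl and of the lipid enzymes were chosen only after the results were seen, whereas the regroupings of samples were planned.

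The slope along size differed between replicate A and the other replicates for 877 genes in footprints by an interaction test in edgeR. Of the 6 footprint libraries with fewer than 150000 reads 0 were of replicate A. That argues against libraries under this limit as the source of the fall of its own footprints along the mRNA size axis. All 6 were of replicates B and C, whose slopes enter the comparison, so their part in the 877 genes stays open. The 70 and 60 fl libraries of replicate A lay above the limit at 155910 and 259590 reads, and how depth acts on a slope was not tested. The fall of replicate A along the mRNA size axis ran from 0.40 at 40 fl (1260461 reads) to -0.73 at 75 fl (918861 reads). Collection of its cells at other sizes than labelled is argued against by its mRNA from the same pools, whose position rose with size (r = 0.807, exact permutation p = 0.0148, n = 8). A reversed sample order of the letter A footprint libraries stays open: of 40320 orders 503 matched the mRNA of B and C as well as the reversed one and 36012 as well as the labelled one, with a mean r of 0.265 for the reversed and 0.334 for the best order. That test largely restates the fall along size and decides nothing; samples were kept as labelled, and no biological explanation was tested.

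Of the 11 genes whose footprints differed across sizes, 10 were highest at 60 fl. A higher level at the cell size of 60 fl was not seen in replicate B, in which 0 of the 10 genes were highest there. That rests on 1 library, with a mean of 5.19, and those of A and C at 60 fl had 9.78 and 10.02, so it excludes nothing. Low depth alone is argued against. The genes' mean in the 5 other shallow libraries was -1.44 log2 relative to the median of the deeper ones. Of the 3 libraries with the excess, only 60 fl replicate C (116437 reads) was shallow. Those of replicate A at 60 fl (259590 reads) and 70 fl (155910 reads) lay above the limit for shallow libraries. They held fewer reads than any other footprint library above it, so a part of low depth stays open. Libraries that carry an excess of FAR11 fragments, at any size, are a candidate explanation, since 10 of 10 genes were more than 1 log2 above their median in 70 fl replicate A as well. What produced that excess was not tested.

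The slope of footprints per mRNA of ACC1, FAS1 and FAS2 was higher in replicate A than the mean of B and C by 0.305 log2 per 5 fl (permutation of letters within sizes, p = 0.00256). The mean slope in B and C was 0.0435 (exact p = 0.759 in B and 0.574 in C), which neither shows nor excludes a smaller rise with cell size in each letter. Whether the footprint order of letter A gave the difference stays open too, for the reason given above for that order. The value at 60 fl was higher than at 40 fl in each replicate, but these sizes were picked as the highest and lowest of the mean. The 60 fl footprint libraries of A and C also carried the FAR11 excess. No biological explanation was tested.

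The unheaded lists are data outside the main measurement, and by Fisher's exact test, adjusted over 12 tests, the genes of 3 lists differed across sizes in mRNA more often than others and those of 1 list less often. In the list of 144 names 77 of 100 counted genes were called (77% against 24.3% outside, adjusted p = 2.92e-26). Of its 144 names 18 were in the ribosome biogenesis list. In the list of 459 names 167 were called (36.4% against 24.2%, adjusted p = 2.66e-07), and in that of 55 names 23 of 55 (41.8% against 25.7%, adjusted p = 0.016). In the list of 585 names the share was lower, at 109 of 576 (18.9% against 27.4%, adjusted p = 3.43e-05). How the submitters chose these lists is not given in the sources used here, so these counts are not independent evidence.

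Sizes were reassigned at random over the libraries, giving 100 regroupings with the real one. For mRNA chance is argued against: the real counts were 856 genes across sizes and 1372 with a slope, and the highest other counts were 173 and 4. In each case 1 regrouping, the real one, reached the real count, and 1 of 100 is the smallest share that these regroupings can give. Across sizes 9 of the others called any gene. For footprints across sizes chance cannot be excluded, as 19 regroupings reached the real count of 11. The highest other was 127, several times as many, and what gave that count was not tested. For translational efficiency across sizes chance cannot be excluded either, as 6 regroupings reached 11 and the highest other was 28. For both slopes the real count was 0, which all 100 regroupings reach, and the highest others were 15 for footprints and 13 for translational efficiency.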

How the results depend on the processing

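The letters taken alone, the fits without the 6 shallow libraries and the list tests without replicate A were chosen after seeing the data. Without the shallow libraries some sizes keep 1 library or none, so no conclusion is drawn from counts across sizes in those fits. Such counts are listed below for footprints only, and they cannot be set against the main count. Counts of mRNA calls kept within 1.5 times of 856 across sizes and 1372 slopes except where named here, and where a value moved the cause was not tested. Across sizes mRNA gave 1394 with DESeq2, 221 without replicate B, 110 without replicate C (823 without A), and 654 to 967 without single libraries. Its slopes numbered 887 without replicate C (1007 without B, 959 without A), 1203 to 1434 without single libraries, and 294, 310 and 309 within letters A, B and C. Footprints across sizes gave 52 with DESeq2, 0 with limma-voom, 621 without replicate A, 15 without B, 0 without C, 0 to 19 without single libraries, 0 without the shallow libraries and 1492 without these and letter A. Their slopes numbered 795 without replicate A, 0 without B or C, 0 to 3 without single libraries, 3 without the size 75 fl, 1415 without letter A and the shallow libraries, and 20, 705 and 129 within letters. Translational efficiency across sizes gave 5 with median-of-ratios factors, 36 with DESeq2, 0 with limma-voom, 35 without replicate A, 6 without B, 0 without C and 0 to 20 without single pools. Its slopes numbered 1 with median-of-ratios factors, 132 with DESeq2, 29 without replicate A, 2 without B, 0 without C, 0 to 7 without single pools, 8 without the size 75 fl, 4 without the shallow pools, 29 without these and letter A, and 655, 1 and 0 within letters.

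With a replicate block by letter the counts were 909 and 1370 for mRNA, 2 and 0 for footprints and 0 and 0 for translational efficiency; with a replicate block by pool the last were 0 and 0. The letters were not taken as pairs, since correlations of same-letter deviations ran from -0.524 to 0.753 for mRNA (mean 0.054) and from -0.847 to 0.775 for footprints (mean 0.0312). As a hint of structure by letter, 13 and 12 of 24 libraries were closest to their own letter.

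List means that passed numbered 4 without replicate B, 3 without C and 9 with the median of the members for mRNA (main 11), 6 without A for footprints and 1, the core histones, without A for translational efficiency (main 0). Gene sets numbered 0 with an estimated correlation in each assay, 0 with fry for footprints and translational efficiency, and without letter A and with an estimated correlation 0, 5 and 0. The slope of SSP1 mRNA was reversed in letter A alone (0.00527). Across genes the relation of footprint to mRNA slopes was reversed with footprints of letter A against mRNA of B (-0.663) and C (-0.683). Among 69 named mRNA slopes 2833 values under alternatives kept direction and side of the threshold, 133 lost the threshold and 1 was reversed. The median slope of all genes was -0.00307 with TMM and 0.00137 with median-of-ratios factors. Of the footprint libraries 6 held under 150000 reads, and in simulated counts 1% of footprint changes of 1 log2 at a single size were recovered; depth was not separated from the spread between replicates.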

Other observations

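Singling out the 6 genes of rising translational efficiency here, and the fit without replicate A that they come from, was done only after the results were seen.

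Genes of mating and of meiosis, which a diploid growing in rich medium is known to repress, were nearly absent from the counted set, with 0 of 25 and 1 of 30 members. In the authors' deposited table of pooled mRNA, the median of the 25 haploid-specific and mating genes was 0.36 at 40 fl, -0.36 at 55 fl and 0.37 at 70 fl. That of 29 meiosis genes was 0.15 at 40 fl, -0.52 at 45 fl and 0.37 at 70 fl, and that of 29 quiescence genes was lowest at 45 fl (-0.94) and highest at 70 fl (0.21). These pooled values have no replicates and were not tested.

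Without replicate A, 6 genes had a rising translational efficiency in edgeR. They were GSY2 (glycogen synthase, slope 0.34 log2 per 5 fl), GPH1 (glycogen phosphorylase, 0.43), HXK1 (a hexokinase, 0.36), HPF1 (0.37), YOP1 (0.44) and TLD1 (0.41). Over all 3 replicates no gene had a slope that passed in edgeR (416 at an unadjusted p under 0.05, 132 in DESeq2 and 0 in limma-voom), so these 6 rest on 2 libraries per size and assay.

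The list of 55 ORF names held all 55 names shared by the lists of 459 and 585. ACC1, FAS1 and FAS2 were in those 3 lists and not in the list of 144.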
